A study of Homo sapiens with 7 samples.

How the data were processed

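Gene expression was measured on 7 Affymetrix arrays, each hybridised with RNA from dendritic-type cells sorted out of the dermis of people with psoriasis. Per the labels' protocols, the epidermis was removed from shave biopsies with dispase, the dermis was cultured further, and the cells that came out were sorted on HLA-DR, CD11c and BDCA-1, the protein product of CD1C. The labels name 2 ways of lysing the cells, Trizol in the design text and RLT buffer with an RNeasy-Micro kit in the extraction protocol, and do not settle which was used. RNA was amplified in 2 cycles of cDNA synthesis and labelled with biotin, per the labels.

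The authors deposited log2 signals per probe set that they had made with GCRMA, per the labels, a method that corrects background from probe sequence, normalises between arrays and summarises probes. No version is stated. The base of the logarithm is not stated either and was taken as 2 from the range of the deposited values, 0.28 to 16.17. No raw scans were used. The table held 22277 probe sets. The platform annotation gave 1 gene symbol to 19033 of them, several to 1022 and none to 2108, and 62 were controls. Symbols were updated through Entrez identifiers in the RefSeq gene table of assembly GRCh38.p14, which 19052 probe sets matched and which changed 9 symbols. No coordinates are given, since no genome was used. To protect the donors, 52 probe sets of sex-linked genes were left out of every step, and genes whose signal can depend on an inherited allele or deletion were not named.

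Each of 11936 genes was represented by the probe set with the highest mean over the 7 arrays, where 4306 genes had 2 or more. Genes above 4 on the log2 scale on at least 3 arrays were tested, which kept 6495 and left out 5441. Arrays have no read depth. Their number limits the precision, and values near or under 4 were read as background. Where no array of the lower group was above 4, the fold is given as a lower bound, from the other group's plain mean down to 4. That mean covers every array of the group. For the BDCA1-negative cells it includes the patient who gave no BDCA1-positive array, so it is no bound for the pairs alone.

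Differences are BDCA1-negative minus BDCA1-positive on the log2 scale, from limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided). P-values were adjusted over all genes tested by the Benjamini-Hochberg method, with a threshold of 0.05. They set a difference against the spread between arrays and do not measure its size. Group means are plain means over arrays with their SD, whereas fitted differences weight the pairs, so the fit can differ from the gap between means. For LAMP3 the BDCA1-negative and BDCA1-positive means were 13.58 and 14.68, and the fitted difference was -0.66. For MNDA the means were 8.96 and 8.43, and the fitted difference had the opposite sign, -0.05. The series calls the groups dependent, and the labels give the patient of each array, so the patient was a random block (duplicateCorrelation) and the array with no partner stayed in. The correlation within patients was 0.574. Deviations from the group means correlated at 0.55, 0.38 and 0.39 within the 3 patients who gave both groups and between -0.39 and 0.15 across patients.

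Gene lists for cell types and functions were fixed before the data were examined, as were the groups, the comparison, the rule for named genes and all alternatives but 1. Of 31 lists, 29 had at least 3 tested members. The endothelial and pericyte list and the melanocyte list had 2 tested members each and were not tested. Lists were tested with limma's cameraPR with a preset correlation between genes of 0.01, two-sided and adjusted over the 29 lists. They were tested again with a correlation estimated for each list and with fry under the same block. Lists share members: CD14 stands in the monocyte and the Toll-like receptor lists, S100A8 and S100A9 in the monocyte and the keratinocyte lists, and MARCO in the macrophage and the C-type lectin lists. FCGR3B stands in the Fc receptor and the neutrophil lists. Genes were named by a rule: the 12 largest differences in each direction among genes past the threshold with the same sign in all 3 pairs, up to 4 members of each list with the smallest adjusted p, and a short fixed set that included the sort markers and the cytokines TNF, IL23A, IL12B and TNFSF10. The CD1 family values beside CD1C fall outside this rule and are given as a check of that gene. CCL19 also falls outside it and was named after its values were seen.

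RNA quality was read from the control probe sets at the 3′ and 5′ ends of ACTB and GAPDH, with an exact two-sided permutation test over the 35 splits of 7 arrays into 4 and 3. The alternatives were no block, a fixed block, no filter, a filter at 6, quantile normalisation, median centring, all probe sets, the mean of a gene's probe sets, eBayes with trend and robust, and each array left out in turn. The ACTB gap as a covariate was added after the data were seen. The code was tested on simulated data with 200 of 6495 genes changed: it recovered 18%, 80%, 88% and 96% of changes of 1, 2, 3 and 4 on the log2 scale, with 10 false calls among 151. With no change simulated it made 0 calls. The simulation drew each gene independently, with 1 correlation for all genes and no background floor, as the fit assumes. It therefore checks the code and does not give the rate of false calls in these data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.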

Results

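The arrays profiled myeloid cells from the dermis of people with psoriasis, sorted as HLA-DR and CD11c double-positive and then parted by BDCA-1. There were 4 BDCA1-negative arrays (replicates 1 to 4) and 3 BDCA1-positive arrays (replicates 1, 2 and 4). A replicate number stands for a patient, so 3 patients gave both populations. Array medians ran from 3.37 to 3.52 on the log2 scale, and 44.8% to 46.8% of probe sets were above 4. BDCA1-positive replicate 1 was the lowest in both. The series is about inflammatory myeloid dendritic cells in psoriasis, and the comparison asks how the BDCA1-negative cells differ in transcripts from the BDCA1-positive cells.

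The genes of the sort were looked at first. CD1C, which encodes BDCA-1, was at background in both populations, with 3.17 ± 0.61 (SD, n = 4) in BDCA1-negative and 3.02 ± 0.20 (SD, n = 3) in BDCA1-positive cells, and no array above 4. Its transcript therefore could not check the labels. HLA-DRA, the alpha chain of HLA-DR, was high in both, at 14.10 ± 0.46 (SD, n = 4) and 14.53 ± 0.39 (SD, n = 3). ITGAX, which encodes CD11c, was present in both and rose in the BDCA1-negative cells by 1.98 ± 0.40 (SE, adjusted p = 0.0307). Among the relatives of CD1C, CD1E averaged 4.49 ± 1.44 (SD, n = 3) in the BDCA1-positive cells, above 4 on 2 of 3 arrays, against 2.71 ± 0.08 (SD, n = 4) in the BDCA1-negative cells. CD1A and CD1B were above 4 on 1 BDCA1-positive array each, and CD207 on none. FCER1A and CD1D were above 4 on no BDCA1-positive array and on 2 of 4 BDCA1-negative arrays each.

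In all, 363 of 6495 genes changed, 289 higher and 74 lower in the BDCA1-negative cells, and 356 of them by at least 2-fold (287 higher, 69 lower). All 363 had the same sign in the 3 patients with both populations. The same pairs went into the fit that picked these genes, so this agreement is not separate evidence. MARCO, a scavenger receptor for bacteria, averaged 7.61 ± 2.09 (SD, n = 4) and was above 4 on no BDCA1-positive array. Its group mean was thus at least 12.2-fold higher (adjusted p = 0.0156 for the fitted difference). MARCO was highest, at 10.05, on BDCA1-negative replicate 3, which has no partner, and ran from 5.79 to 8.66 on the others. FCAR, the Fc receptor for IgA, was at least 15.2-fold higher (adjusted p = 0.00593). HPSE, the heparanase that cleaves heparan sulfate, rose by 4.75 ± 0.52 (SE, adjusted p = 0.00815) and HS3ST1, which sulfates the same sugar chains, by 4.38 ± 0.33 (SE, adjusted p = 0.00416). VSIG4, a complement receptor of macrophages, rose by 4.69 ± 1.06 (SE, adjusted p = 0.0443), and the formyl peptide receptor FPR2 by 4.53 ± 0.49 (SE, adjusted p = 0.00812). NLRP3, the inflammasome sensor, rose by 4.60 ± 0.71 (SE, adjusted p = 0.0162), and the mean of its probe sets differed by 2.26 (adjusted p = 0.0717). ITGAM, which encodes CD11b, rose by 4.32 ± 0.82 (SE, adjusted p = 0.0264), or by 2.18 as the mean of its probe sets. ADGRE3, an adhesion receptor of myeloid cells, TNS1, a focal adhesion protein, the secreted protease HTRA1 (at least 18.5-fold higher) and SOWAHC (at least 11.7-fold higher) completed the 12 largest. The mean of TNS1's probe sets missed the threshold, at 1.44 (adjusted p = 0.0558). HS3ST1, FPR2 and NLRP3 averaged 3.65, 3.69 and 3.48 in the BDCA1-positive cells, above 4 on 1 of 3 arrays each, so the sizes of their differences rest partly on background values.

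In the other direction, DOK5, an adaptor of receptor tyrosine kinases, averaged 6.44 ± 1.04 (SD, n = 3) in the BDCA1-positive cells and was above 4 on no BDCA1-negative array, at least 5.43-fold lower (adjusted p = 0.00507). ALOX15B, a lipoxygenase of arachidonic acid, fell by 2.95 ± 0.29 (SE, adjusted p = 0.00593). CD70, the ligand of CD27 on T cells, was at least 1.85-fold lower (adjusted p = 0.0162). The mitotic kinase TTK fell by 2.87 ± 0.49 (SE, adjusted p = 0.0192), to a mean of 3.70 that was above 4 on 1 of 4 BDCA1-negative arrays. ST8SIA1, which makes the ganglioside GD3, fell by 2.44 ± 0.37 (SE, adjusted p = 0.0162), and the secreted proteins FSTL1 and MIA fell by 2.59 and 2.77. The exchange factor MCF2 (-2.88, or -0.96 with adjusted p = 0.0726 as the mean of its probe sets), SEZ6L (at least 2.96-fold lower), the dynein chain DNAI2 (at least 3.48-fold lower), LMCD1 (-2.23) and the polarity gene VANGL1 (-2.12, to a mean of 3.58) were the others of the 12 largest decreases. MIA and LMCD1 averaged 4.35 and 4.22 in the BDCA1-negative cells, above 4 on 1 of 4 arrays each. The sizes of their differences thus rest partly on background values. The count of changed genes was not stable: it was 11 with no block, 203 with a fixed block, 1 with no filter and 2 with the ACTB gap described at the end as a covariate. Leaving out 1 array gave 99, 221, 276 and 191 genes for BDCA1-negative replicates 1 to 4, and 0, 132 and 149 for BDCA1-positive replicates 1, 2 and 4. The count of 0 in limma stood beside 1255 genes at an unadjusted p under 0.05, against 1512 with all arrays.

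**Figure D1:**
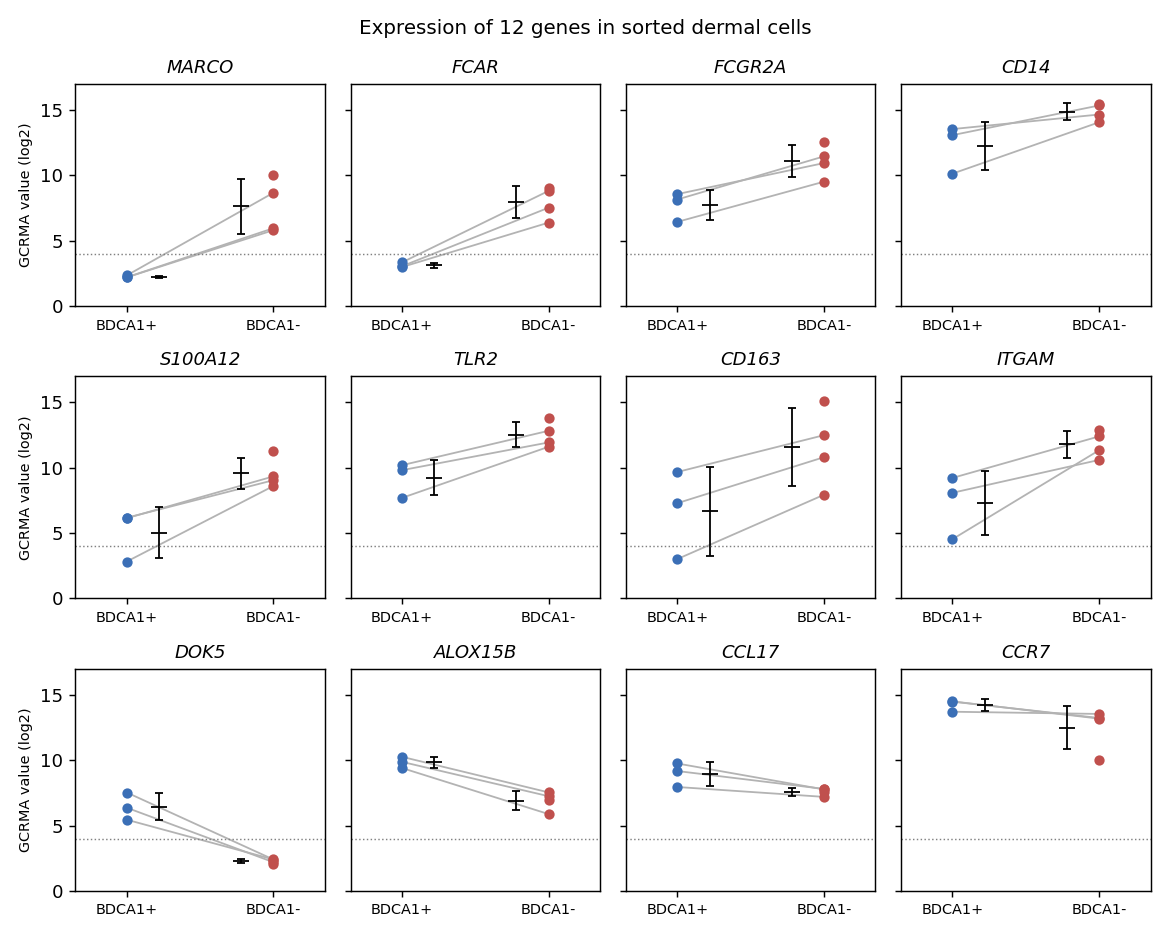
Log2 signal of named genes on each array, with BDCA1-negative (n = 4) and BDCA1-positive (n = 3) arrays as points and group means with SD, and the filter value of 4 as a dotted line. MARCO and FCAR lay above 4 on all 4 BDCA1-negative arrays and on no BDCA1-positive array.

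The lists of monocyte and macrophage markers had medians above 0, and part of their members rose in the BDCA1-negative cells. Of 15 monocyte markers measured, 8 rose over all genes tested, 11 adjusted over the list alone, and none fell. S100A12, an alarmin of monocytes and neutrophils, rose by 4.19 ± 0.68 (SE, adjusted p = 0.0172), the matrix proteoglycan VCAN by 3.40 ± 0.51 (SE), CD93 by 2.95 ± 0.35 (SE) and TREM1, which amplifies inflammatory signals, by 2.77 ± 0.35 (SE). CD14, the endotoxin co-receptor, was high in both populations, at 14.87 ± 0.66 (SD, n = 4) and 12.23 ± 1.85 (SD, n = 3), and rose by 2.52 ± 0.57 (SE, adjusted p = 0.0434). Without BDCA1-positive replicate 1 its difference was 1.63 (adjusted p = 0.130). The monocyte list had a median of 2.77 (adjusted p = 8.16e-11, and adjusted p = 0.0799 with an estimated correlation). Of 22 macrophage markers 8 rose, 15 adjusted over the list alone, among them CHI3L1, a chitinase-like protein (3.51 ± 0.47, SE), GPNMB (3.25 ± 0.63, SE) and the transcription factor MAF (3.01 ± 0.58, SE). As the mean of their probe sets CHI3L1 rose by 1.76, and MAF was at 1.74 (adjusted p = 0.0555). CHI3L1 was above 4 on 1 of 3 BDCA1-positive arrays. The macrophage list had a median of 3.13 (adjusted p = 1.73e-10, and adjusted p = 0.132 with an estimated correlation), or 1.43 with the ACTB gap as a covariate. CD163, the haemoglobin scavenger receptor, did not pass, at 4.25 ± 1.16 (SE, adjusted p = 0.0781), and ranged widely within both groups (SD 3.01 and 3.38). It passed with a fixed block (3.75, adjusted p = 0.0347) and with a filter at 6 (4.20, adjusted p = 0.0429).

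The Fc receptor list shifted the same way. All 6 measured were above 0, and 5 rose over all genes tested, 6 adjusted over the list alone. FCGR2A (CD32A) rose by 3.12 ± 0.48 (SE, adjusted p = 0.0162), the inhibitory receptor FCGR2B by 3.68 ± 0.65 (SE, adjusted p = 0.0215) and FCER1G, the shared signalling chain, by 2.74 ± 0.49 (SE, adjusted p = 0.0215). The list had a median of 3.05 (adjusted p = 2.54e-09, and adjusted p = 0.0236 with an estimated correlation). Of 17 C-type lectin and scavenger receptors 6 rose, 10 adjusted over the list alone, including CLEC4A (3.83 ± 0.56, SE) and the fungal and bacterial lectin CLEC4E, at least 4.35-fold higher (adjusted p = 0.00925). Their median was 2.82, or 2.61 with members at background set to their bounds (adjusted p = 1.52e-08, and adjusted p = 0.0799 with an estimated correlation), and 1.17 with the ACTB gap as a covariate. Of 12 neutrophil markers on the array only 3 passed the filter. Of these MMP9 and FPR2 rose, 3 adjusted over the list alone, with a median of 2.45 (adjusted p = 8.29e-05, and adjusted p = 0.0192 with an estimated correlation). The third was FCGR3B, which also stands in the Fc receptor list. FPR2 and FCGR3B averaged 3.69 and 3.37 in the BDCA1-positive cells, which is background. With no filter the median of the neutrophil list was 0.25.

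**Figure D2:**
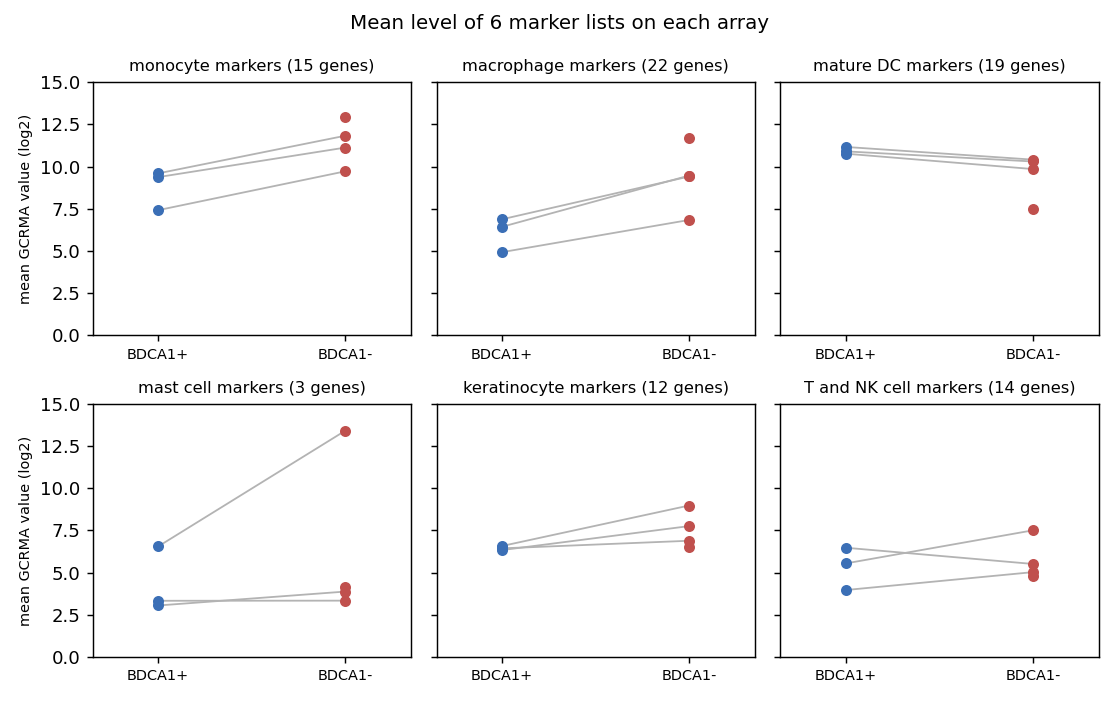
Mean log2 signal of marker lists on each array, by group and replicate. BDCA1-negative replicate 3 had the highest mean of macrophage markers, 11.70, and the lowest of mature dendritic cell markers, 7.46, and BDCA1-negative replicate 1 had a mean of mast cell markers of 13.42.

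The lists for chemokines, Toll-like receptors and complement had medians above 0. Among 16 chemokines, 5 rose and 1 fell (7 and 1 adjusted over the list alone). CXCL2 rose by 1.98 ± 0.23 (SE, adjusted p = 0.00901), CXCL3 by 2.50 ± 0.31 (SE, adjusted p = 0.00925) and CXCL5 by 1.32 ± 0.28 (SE, adjusted p = 0.0377), or 2.37 as the mean of its probe sets, all attractants of neutrophils. CCL20, which attracts CCR6-bearing T cells, rose by 2.13 ± 0.42 (SE, adjusted p = 0.0294), and the 1 that fell was CCL17. The chemokine list had a median of 1.24 (adjusted p = 0.00170, and adjusted p = 0.0656 with an estimated correlation), and missed the threshold without BDCA1-negative replicate 1 (median 1.42, adjusted p = 0.0678). With no filter its median was 0.82. Of 11 Toll-like receptors and adaptors 3 rose, 6 adjusted over the list alone (1 lower). They were TLR2 (3.07 ± 0.49, SE, adjusted p = 0.0168), the peptidoglycan sensor NOD2 (2.48 ± 0.43, SE) and CD14. This list had a median of 1.24 (adjusted p = 0.00548, and adjusted p = 0.333 with an estimated correlation), or 0.69 without BDCA1-positive replicate 1. With the ACTB gap as a covariate it missed the threshold (0.46, adjusted p = 0.0881). Of 13 complement genes 3 rose, 4 adjusted over the list alone: C3 by 3.49 ± 0.68 (SE) from a BDCA1-positive mean of 3.91, its receptor C3AR1 by 3.49 ± 0.60 (SE), and ITGAM. C1QA was at 3.85 ± 1.20 (SE, adjusted p = 0.111), from a BDCA1-positive mean of 3.27, which is background. The complement list had a median of 1.46 (adjusted p = 0.0158, and adjusted p = 0.333 with an estimated correlation). Its median was 2.42 without BDCA1-negative replicate 1, 0.22 with the ACTB gap as a covariate, and 1.46 (adjusted p = 0.0513) without BDCA1-negative replicate 2.

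The lists for matrix metalloproteinases, for lysosomes and lipids, and for glycolysis and hypoxia also had medians above 0. Of 15 matrix metalloproteinases and inhibitors 3 rose and 1 fell (6 and 1 adjusted over the list alone). ADAMDEC1 rose by 3.11 ± 0.38 (SE, adjusted p = 0.00925), PLAUR, the urokinase receptor, by 2.69 ± 0.42 (SE, adjusted p = 0.0162) and MMP9 by 2.18 ± 0.45 (SE, adjusted p = 0.0321), whereas MMP25 fell by 1.12 ± 0.21 (SE, adjusted p = 0.0270), or was at -0.55 (adjusted p = 0.0918) as the mean of its probe sets. The list had a median of 1.29 (adjusted p = 0.000434, and adjusted p = 0.0520 with an estimated correlation). Of 24 lysosome and lipid genes 6 rose, 12 adjusted over the list alone, among them the proteases CTSD (3.21 ± 0.53, SE) and CTSL (2.37 ± 0.46, SE), the lipase LIPA (2.46 ± 0.47, SE) and the cholesterol exporter ABCA1 (1.61 ± 0.31, SE). Their median was 1.17 (adjusted p = 7.45e-06, and adjusted p = 0.363 with an estimated correlation), or 0.69 without BDCA1-positive replicate 1 and 0.59 with the ACTB gap as a covariate. Of 26 glycolysis and hypoxia genes 3 rose, 12 adjusted over the list alone. The 1 enzyme of glycolysis among the 3 was hexokinase HK2, by 2.91 ± 0.30 (SE), and the others were ADM, the vasodilator peptide adrenomedullin, by 2.55 ± 0.46 (SE) and the carbonic anhydrase CA12 by 2.37 ± 0.44 (SE). As the mean of their probe sets HK2 rose by 1.47 and CA12 by 1.58. Their median was 0.74 (adjusted p = 1.97e-05, and adjusted p = 0.149 with an estimated correlation), or 0.28 with the ACTB gap as a covariate.

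Markers of mature dendritic cells shifted the other way, with 18 of 19 below 0 and a median of -1.24 (adjusted p = 0.000303, and adjusted p = 0.363 with an estimated correlation). Within the pairs the median was smaller, at -0.63, -0.74 and -0.95 for replicates 1, 2 and 4. BDCA1-negative replicate 3, which has no partner, had a list mean of 7.46, against 9.85 to 10.41 on the other BDCA1-negative arrays. Only CCL17, an attractant of T cells, passed as a single gene, and it fell by 1.37 ± 0.31 (SE, adjusted p = 0.0418), the 1 decrease also adjusted over the list alone. CCR7, which guides cells to lymph nodes, was at -1.26 ± 0.58 (SE, adjusted p = 0.236), RELB at -1.47 ± 0.41 (SE, adjusted p = 0.0821) and LAMP3 at -0.66 ± 0.53 (SE, adjusted p = 0.494). LAMP3 was high in both populations, at 13.58 ± 1.56 (SD, n = 4) and 14.68 ± 0.45 (SD, n = 3). The list's median was 0.28 (adjusted p = 0.310) with the ACTB gap as a covariate. Of 13 cell cycle genes TTK and MCM5, a part of the replicative helicase (-1.06 ± 0.24, SE, adjusted p = 0.0463), fell, 2 adjusted over the list alone. That list had a median of -0.36 (adjusted p = 0.0302, and adjusted p = 0.265 with an estimated correlation). It missed the threshold with a fixed block (median -0.32, adjusted p = 0.0698), with no filter (0.00, 0.184) and with the ACTB gap (-0.046, 0.191). It also missed it without BDCA1-negative replicate 1 (-0.31, 0.0742), BDCA1-negative replicate 3 (-0.32, 0.0607) or BDCA1-positive replicate 1 (-0.53, 0.0602).

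**Figure D3:**
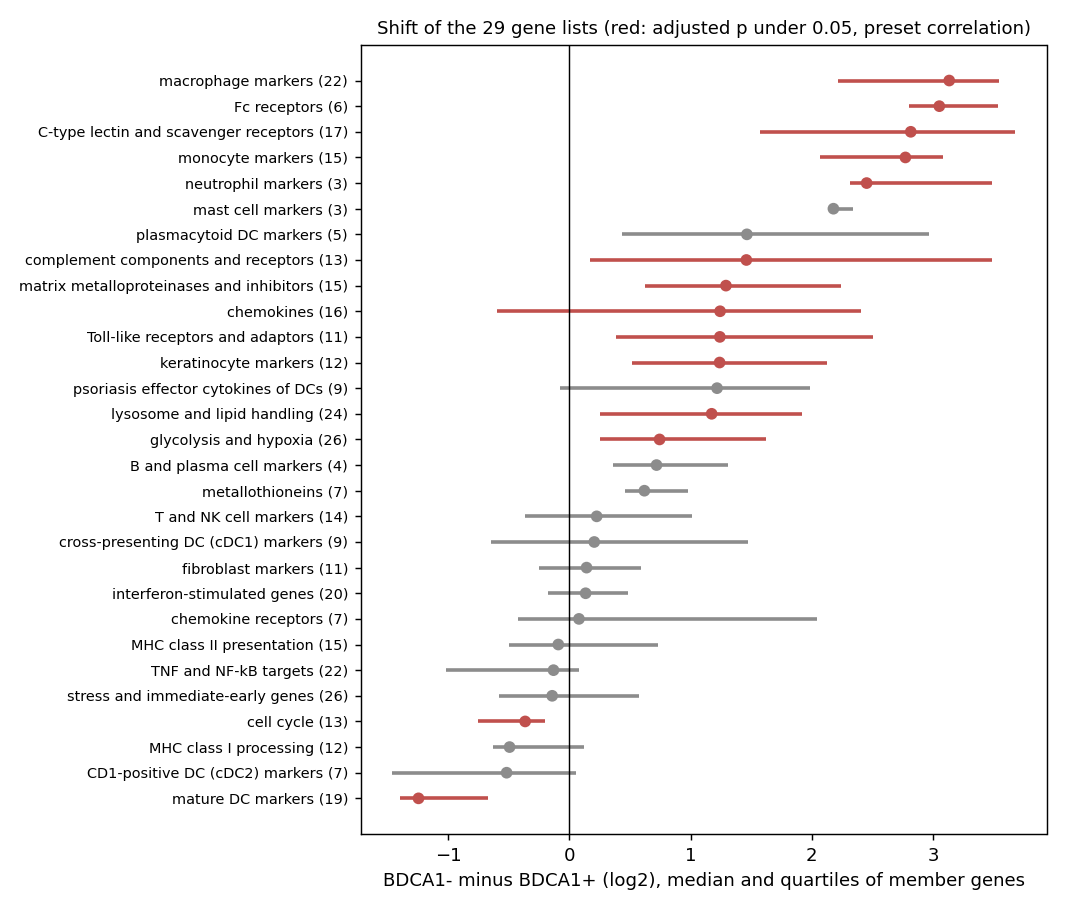
Median log2 difference of each tested gene list, BDCA1-negative minus BDCA1-positive, with the quartiles of its members. Macrophage markers had the highest median, 3.13, and mature dendritic cell markers the lowest, -1.24.

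The cytokines by which dendritic cells act in psoriasis did not pass the test as a list. None of 9 measured passed over all genes tested, 3 higher and 1 lower adjusted over the list alone, with a median of 1.22 (adjusted p = 0.248). It passed with a fixed block (1.28, adjusted p = 0.0101) and with the ACTB gap as a covariate (1.07, adjusted p = 0.000598), and was at 0.41 (adjusted p = 0.530) with no filter. The smallest adjusted p of the 9 was that of IL15, the 1 that was lower, at -1.57 ± 0.50 (SE, adjusted p = 0.116). TNF was at 1.98 ± 0.70 (SE, adjusted p = 0.144), from a BDCA1-positive mean of 3.36, which is background. The death ligand TNFSF10 (TRAIL) was at 2.60 ± 1.02 (SE, adjusted p = 0.176), IL1B at 1.46 ± 0.48 (SE, adjusted p = 0.124) and IL23A at -0.49 ± 0.88 (SE, adjusted p = 0.776). Without BDCA1-negative replicate 3 IL1B passed, at 1.74 (adjusted p = 0.0237). NOS2, the inducible nitric oxide synthase, was at background on every array, at 2.01 ± 0.02 (SD, n = 4) and 2.00 ± 0.00 (SD, n = 3). IL12B was above 4 on 1 BDCA1-positive array and on no other. Of 20 interferon-stimulated genes none passed, none adjusted over the list alone, with a median of 0.14 (adjusted p = 0.742). The closest were SAMHD1 at 2.57 ± 0.62 (SE, adjusted p = 0.0523) and EIF2AK2 at 1.47 ± 0.39 (SE, adjusted p = 0.0719). Both passed with a filter at 6 (adjusted p = 0.0290 and 0.0455), and SAMHD1 also with eBayes with trend and robust (0.0427) and without BDCA1-negative replicate 1 (3.43, 0.0467). Of 22 TNF and NF-kB targets 2 rose, 2 adjusted over the list alone: the prostaglandin synthase PTGS2 by 2.15 ± 0.43 (SE) and TNFAIP6 by 2.40 ± 0.50 (SE), in a list with a median of -0.13 (adjusted p = 0.387).

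The lists for subsets of dendritic cells and for antigen presentation did not pass the test. Of 13 markers of CD1-positive dendritic cells on the array, 7 were past the filter. CD1A, CD1B, CD1E, CD207 and FCER1A were not, so the list test held no CD1 gene. None of the 7 passed, none adjusted over the list alone, with a median of -0.52 (adjusted p = 0.346). That median was -1.58 without BDCA1-negative replicate 1, -0.25 without BDCA1-negative replicate 2 and -0.055 with the ACTB gap as a covariate, and none of these passed. FLT3, the receptor for a dendritic cell growth factor, was at -1.31 ± 0.48 (SE, adjusted p = 0.155), IRF4 at -1.63 ± 0.70 (SE, adjusted p = 0.213) and CLEC10A at 1.57 ± 0.74 (SE, adjusted p = 0.244). Without BDCA1-negative replicate 3 IRF4 passed, at -1.17 (adjusted p = 0.0374). Of 9 markers of cross-presenting dendritic cells THBD rose, by 2.77 ± 0.57 (SE, adjusted p = 0.0325), with 2 higher and 1 lower adjusted over the list alone and a median of 0.21 (adjusted p = 0.721). BATF3 was at -2.09 ± 0.51 (SE, adjusted p = 0.0559) and IRF8 at 1.47 ± 0.43 (SE, adjusted p = 0.0909). BATF3 passed with a filter at 6 (adjusted p = 0.0319) and with quantile normalisation (0.0473). Of 15 genes of MHC class II presentation the proteases CTSD and CTSS (2.05 ± 0.47, SE, or 2.01 with adjusted p = 0.0583 as the mean of its probe sets) rose, with 2 higher and 1 lower adjusted over the list alone. That list had a median of -0.09 and a test in the upward direction (adjusted p = 0.740). Of 12 genes of MHC class I processing none passed, none adjusted over the list alone, with a median of -0.49 (adjusted p = 0.130, or 0.0230 with no filter). That median was -0.24 without BDCA1-negative replicate 4 and -0.27 where each gene was the mean of its probe sets. TAP1, the peptide transporter, was at -0.64 ± 0.23 (SE, adjusted p = 0.152).

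Markers of other skin and blood cells differed between arrays. Of 12 keratinocyte markers 3 rose, 3 adjusted over the list alone: S100A8 by 2.34 ± 0.38 (SE, adjusted p = 0.0174) and S100A9 by 3.08 ± 0.55 (SE, adjusted p = 0.0221), calcium-binding alarmins that monocytes also make, and KRT10 by 1.29 ± 0.29 (SE, adjusted p = 0.0445). The mean of KRT10's probe sets missed the threshold (adjusted p = 0.0511). Their median was 1.24 (adjusted p = 0.00621, and adjusted p = 0.132 with an estimated correlation), or 0.44 (adjusted p = 0.225) without BDCA1-negative replicate 1 and 0.70 with no filter. That array stood apart in mast cell markers, with a list mean of 13.42 against 3.34 to 4.15 on the other BDCA1-negative arrays. BDCA1-positive replicate 1 was at 6.55, and the other BDCA1-positive arrays at 3.05 and 3.33. The mast cell list of 3 genes had a median of 2.18 (adjusted p = 0.421), none past the threshold and none adjusted over the list alone. KIT, the receptor for stem cell factor, was at 2.51 ± 1.59 (SE, adjusted p = 0.385) and the protease CPA3 at 2.18 ± 1.82 (SE, adjusted p = 0.510), and without that array they were at -0.072 and -0.54.

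Of 11 fibroblast markers SPARC rose, by 2.86 ± 0.45 (SE, adjusted p = 0.0162, or 2.22 with adjusted p = 0.0563 as the mean of its probe sets), 1 higher and 1 lower adjusted over the list alone, with a median of 0.14 (adjusted p = 0.742). Of 14 T and NK cell markers NKG7 rose, by 2.46 ± 0.56 (SE, adjusted p = 0.0450) from a BDCA1-positive mean of 3.45, 1 adjusted over the list alone, with a median of 0.23 (adjusted p = 0.599). That list passed without BDCA1-positive replicate 4 (1.15, adjusted p = 0.0454) and with the ACTB gap as a covariate (0.94, adjusted p = 0.0334), and was at -0.29 (adjusted p = 0.725) without BDCA1-negative replicate 1. Of 5 markers of plasmacytoid dendritic cells NRP1 rose, by 3.57 ± 0.59 (SE, adjusted p = 0.0183), or 2.36 as the mean of its probe sets, 3 higher and 1 lower adjusted over the list alone, with a median of 1.46 (adjusted p = 0.149), 2.09 (adjusted p = 0.0197) without BDCA1-positive replicate 2, and 0.0026 (adjusted p = 0.489) with no filter. None of 4 B and plasma cell markers passed, 2 adjusted over the list alone, with a median of 0.72 (adjusted p = 0.225). That list too passed without BDCA1-positive replicate 4 (1.28, adjusted p = 0.0396) and with the ACTB gap (1.26, adjusted p = 0.0131), and was at 0.26 (adjusted p = 0.0959) with no filter.

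RNA quality was compared in 2 control genes. The gap between the 3′ and 5′ probe sets of ACTB was 3.41 ± 1.10 (SD, n = 4) in BDCA1-negative and 2.01 ± 0.22 (SD, n = 3) in BDCA1-positive cells, larger on every BDCA1-negative array than on every BDCA1-positive array (exact permutation p = 0.0571, where the smallest possible was 0.0286). The same gap for GAPDH was 1.90 ± 0.27 (SD, n = 4) and 1.79 ± 0.17 (SD, n = 3), with an exact permutation p of 0.686. From the 3′ to the middle probe set the ACTB gap was 1.73 ± 1.01 (SD, n = 4) and 0.65 ± 0.29 (SD, n = 3). There the arrays of both groups overlapped (exact permutation p = 0.171). These tests ignore the pairs. The 3′ to 5′ gap of ACTB was 2.84 against 2.05 in replicate 1, 2.33 against 1.77 in replicate 2 and 3.61 against 2.21 in replicate 4. That gap, used as the covariate, was widest, at 4.85, on BDCA1-negative replicate 3, which also had the most macrophage signal and the least mature dendritic cell signal.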

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

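Of the tests in this part, those of a single array carrying the shift, of changed genes with 1 tested probe set, of a share of macrophages or monocytes, of the splits for the 4 lists and of lost CD1 transcripts were chosen only after the result was seen. The ACTB gap became a covariate after the gap was seen, and fry's p was added after that fit.

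CD70 lay apart on 1 of the 4 BDCA1-negative arrays, with 3.17 against 2.32 to 2.38, a gap of 0.932 of the range, although all 4 values were under 4 and so within background. LMCD1 did so with 5.48 against 3.69 to 3.89, a gap of 0.886. CCR7 was 10.01 on BDCA1-negative replicate 3 against 13.18 to 13.53, a gap of 0.898. On the same array IRF4 was 6.07 against 10.01 to 10.61, a gap of 0.869, and IL1B was 11.76 against 14.31 to 14.47, a gap of 0.943. MAF was 9.82 on BDCA1-negative replicate 1 against 12.74 to 13.32, a gap of 0.832. On that array MMP9 was 12.96 against 14.18 to 14.41, a gap of 0.845, and ADAMDEC1 was 10.70 against 12.52 to 12.81, a gap of 0.862. KIT was 13.84 there against 3.73 to 5.36, a gap of 0.839, and the mean of the mast cell list was 13.42, a gap of 0.919. These were 10 of 119 genes and lists examined, where a gap past the critical value of Dixon's test arises by chance in about 1 group of 20. Among 1204 probe sets with no or several gene symbols, which no comparison used, 2 passed the threshold, 1 of them higher in the BDCA1-negative cells.

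Markers of monocytes, macrophages, Fc receptors and C-type lectins were higher in the BDCA1-negative cells, with a median of 2.83 (quartiles 2.15 and 3.44) over 53 genes. A single array as the cause was argued against, since with any 1 array left out the lowest median of the 4 lists was 2.14, and the lowest within any pair was 1.57. RNA quality may account for part, although the GAPDH gap overlapped between the groups (exact permutation p = 0.686). With the ACTB gap as a covariate the median was 1.66 (quartiles 0.70 and 2.30), the median SE went from 0.65 to 0.80, and fry's p for these genes went from 0.00471 to 0.102. The ACTB gap was larger on every BDCA1-negative array, so as a covariate it takes up part of any group difference. The fit therefore cannot decide. The bound written after the gap was seen but before this fit was run, a median above 1 with all 4 lists past, was met, but the lower quartile was under 1 and the preset correlation understates the link between genes, so RNA quality stays open. A share of macrophages or monocytes, which carry HLA-DR and can carry CD11c and so could pass the gate, cannot be told apart from a BDCA1-negative dendritic cell with these genes: CD14 averaged 14.87 and the mature list was lower in each pair, with a median of -0.74, as either would give; 2 of 35 splits of the arrays gave a mean difference as large over these genes (2.89, highest other 3.25), so chance was not excluded, and among the 8 splits that part all 3 pairs, too few for a share under 0.05, the highest other was 1.63.

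The count of 363 changed genes, 356 of them by at least 2-fold, was set against faults of single probe sets and against chance. Of the 363, 106 had another probe set past the filter. Of these 145 other probe sets 98.6% had the same sign, which argues against faulty probe sets there, and 60 also passed. Probe sets under the filter were not counted, so that share leaves them out. The other 257 genes had no other tested probe set and stay open. Some of them had others under the filter: as the mean of all probe sets NLRP3 went from 4.60 to 2.26, ITGAM from 4.32 to 2.18 and MCF2 from -2.88 to -0.96. Of 35 splits, 1 gave as many genes, the real one, with a highest other of 9, and 1 gave as many 2-fold changes, with a highest other of 9. As patients pair the arrays, the fair comparison is with the 8 splits that part all 3 pairs, where the highest other was 3 genes, and 8 splits are too few for a share under 0.05. For the 14 shifted lists 5 of 35 splits gave as many, with a highest other of 16, so chance cannot be excluded for that count.

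CD1C was near background in cells sorted for its protein. A failed CD1C probe set stays open: of CD1A, CD1B, CD1E, FCER1A and CD207, 0 were above 4 on all 3 BDCA1-positive arrays, which the bound set beforehand took as evidence against it, but that bound passed over CLEC10A, FLT3 and IRF4, markers of the same cells that were above 4 on every array. Loss of CD1 transcripts as the cells matured in culture may account for it and was not decided. LAMP3, CCR7 and CCL19 ranked within the top 0.285%, 0.553% and 26.7% of genes on every BDCA1-positive array, but ranks compare probe sets that can differ in affinity, and no immature cells were measured. No other biological explanation was tested.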

How the results depend on the processing

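The ACTB gap as a covariate was chosen after the data were seen, and all other tests before. As that gap separates the groups, a fit with it takes up part of any difference between them, whatever its cause. Of 363 changed genes (356 by at least 2-fold), 11 (11) were called with no replicate block, all among the 363, and 203 (203) with a fixed replicate block, 175 of them among the 363. With no filter 1 (0) passed of 11936 tested, where 1409 had an unadjusted p under 0.05, and with the ACTB gap 2 (2). Leaving out 1 array gave 0 to 276 (0 to 274). The cause was not tested, except that each omission leaves fewer arrays. The 14 shifted lists were 2 with an estimated correlation, which allows for linked genes, 7 by fry, and 11 to 16 with 1 array left out. The 2 were the Fc receptor and neutrophil lists. By fry these 2 passed again, with the monocyte, macrophage, C-type lectin, metalloproteinase, and glycolysis and hypoxia lists. Neither list that shifted down passed by fry (adjusted p = 0.190 for mature dendritic cells and 0.0686 for cell cycle). The filter at 6, both scalings, all probe sets, the mean of probe sets and eBayes with trend and robust gave 320 to 461 genes. Quantile normalisation moved the median of all genes to -0.12 and the share of higher calls from 79.6% to 69.4% (301 higher, 133 lower).

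None of the 70 named genes past the threshold changed sign. They kept their call in 50 cases with a fixed replicate block, 4 with none, 26 without BDCA1-negative replicate 1, 57 without BDCA1-negative replicate 3, and 0 with no filter, with the ACTB gap or without BDCA1-positive replicate 1. With the ACTB gap the mature dendritic cell list turned to 0.28, IL23A to 0.84, LAMP3 to 0.79, CCR7 to 0.24, IRF4 to 0.22 and CLEC10A to -0.42. With 1 array left out KIT ran from -0.072 to 3.83, CPA3 from -0.54 to 3.36, and the GAPDH gap difference from -0.017 to 0.19, and the ACTB gap difference stayed between 0.917 and 1.76. The fixed replicate block changed 2 list calls, cell cycle (lost) and psoriasis cytokines (gained), and CD163 passed with it. With the ACTB gap the lists for psoriasis cytokines, T and NK cells, and B and plasma cells also passed, at 1.07, 0.94 and 1.26. As the mean of their probe sets 9 of 67 named genes lost their call. Signal over background limits CD1C, NOS2 and IL12B, which were not tested.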

Other observations

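The list tests of this part were planned, and the values in its last paragraph were chosen after they were seen. Stress and immediate-early genes, which respond to handling of cells, did not shift as a list of 26. Its median was -0.14 and its mean 0.10 (adjusted p = 0.990), with 1 gene higher over all genes tested and none adjusted over the list alone. The 1 was FOS, a part of the AP-1 transcription factor, which rose by 2.79 ± 0.64 (SE, adjusted p = 0.0465). It was again at 2.79, with an adjusted p of 0.0510, where each gene was the mean of its probe sets. Metallothioneins, which bind zinc and copper, had 6 of 7 members above 0, none past the threshold and none adjusted over the list alone, with a median of 0.62 (adjusted p = 0.180). Without BDCA1-positive replicate 1 that median was 1.10 (adjusted p = 0.00560), and without BDCA1-positive replicate 4 it was 0.12 (adjusted p = 0.705). Of 7 chemokine receptors none passed over all genes tested, 2 adjusted over the list alone, with a median of 0.08 (adjusted p = 0.721).

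CPA3, KIT and GATA2, the 3 mast cell markers measured, reached 13.9, 13.8 and 12.5 on BDCA1-negative replicate 1. The largest axis of variation held 47.4% of the variance and the next 19.8%, and BDCA1-negative replicate 3 and BDCA1-positive replicate 1 lay at its ends, at 87.3 and -70.3.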
